A study of Mus musculus with 6 samples.

How the data were processed

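RNA was sequenced from livers of 6 male C57BL/6N mice, 3 per diet, and the labels describe littermates sampled as separate animals. Per the labels, RNA was extracted with miRNeasy kits, libraries were made with the TruSeq stranded total RNA kit after Ribo-Zero depletion, and reads came from a NextSeq500 as 75-base pairs. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.7.3a and genes were counted in Partek 9. The values deposited by the authors were estimated counts (expected counts) per gene, on a linear scale and not normalized, and 22.4% of them were not whole (tolerance 0.01). The counting method's settings, including strand, and its annotation are not given in the sources used here.

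The table held 20107 genes, of which 14843 were protein coding, 1925 lncRNA and 2285 pseudogenes by the gene types it gives. In 19547 cases the end given was 1 base past that of GENCODE M21, and coordinates are printed with that base taken off. Of 21 symbols that spreadsheet software had turned into dates, 19 were restored by coordinates. The table held no mitochondrially encoded gene. BLAST 2.17.0 found 15 pseudogenes whose transcripts match mitochondrial transcripts (identity of at least 90% over at least 50% of the length), and their share of counts was used as a library measure.

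Expected counts were rounded, and genes were kept by filterByExpr with its minimum count of 10, which left 14896. The comparison used edgeR 4.0.16 with TMM factors (0.9705 to 1.0216) and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. No covariate was used, since the labels give no batch, litter or pairing. The p values measure the spread between these animals. Levels are CPM on TMM-scaled library sizes. The square root of the common dispersion was 0.121. One read stood for 0.0324 to 0.0374 CPM, and a floor of 3 counts for 0.097 to 0.112 CPM, which covers counting error alone.

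Before the values were seen, 41 gene lists with 834 entries were fixed, of which 795 matched by symbol, 7 by synonym and 32 were not in the table. Each list with at least 3 tested members, 39 in all, was tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, and again with an estimated correlation. Mitochondrially encoded genes and pancreatic acinar markers had too few members to test. Members were also counted at an adjusted p under 0.05 over all genes and adjusted over the list alone.

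Named genes followed a rule fixed before the values were seen. It took the 8 largest changes in each direction among called genes with at least 5 CPM in the higher diet and all libraries apart, without predicted or clone names. It took from each list up to 3 called members by smallest p in the direction with more of them and up to 1 in the other, or the member with the smallest p where none was called. It always took Fasn, Scd1, Srebf1, Pparg, Cd36, Cidec, Fgf21, Khk, Pck1, Cyp7a1 and 1 further gene. Some genes that the rule gave are not reported here. The rule gave 102 genes, and 29 more were chosen after their values were seen. Of the 131, 9 share at least 20% of their exonic bases with another gene and 29 had values that were not whole in all 6 libraries. Genes with such values included Fads2, Plin2, Acaa1b, Cpt1a, Oas1a, Tkfc and Aqp8. They also included Hal, Gls2, Pck1, Cyp1a2, Hc, Hba-a1 and Rpl5. The levels of the genes listed here are uncertain as well, though they are not marked again below.

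Library measures were compared by an exact permutation test over the 20 assignments of libraries to diets. Alternatives planned before the values were seen were other size factors, filters, DESeq2 1.42.0, limma-voom with and without sample weights, the 10 most abundant genes left out, stricter thresholds, each library left out in turn, and lists without shared members. Added afterwards were fits without the pseudogenes that match mitochondrial transcripts, with an index of clock phase as a covariate, and with each library's trend on GC content and transcript length taken out. The index was the mean log2 CPM of Per2, Per3 and Dbp minus that of Arntl, Npas2 and Clock, centered over the libraries. R 4.3.3, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.

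The analysis was tested on simulated data with 14896 genes, 200 of them changed. The edgeR fit recovered 36 of 67 genes changed 1.5-fold, 56 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 11 of its 168 calls were false. Simulated counts were whole, independent between genes and drawn at the trended dispersion. They held no deviating library and no trend on GC content or length, so these rates may not hold for the real data. All 6 libraries were used in the reported fit. Genes below the count filter entered the library measures but not the tests.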

Results

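The data were gene-level read counts from livers of 6 male C57BL/6N mice aged 16 weeks. Littermates had free access, from 8 weeks of age and for 8 weeks, either to chow or to the HFHC regimen, a high-fat, high-calorie food containing fructose with a high-fructose drink beside it. Each diet had 3 mice and 3 libraries. The HFHC libraries (replicates 1, 2 and 3) held 30096409 to 30871297 counts and the Chow libraries (replicates 7, 8 and 9) held 26767416 to 27339613. The single comparison the design implies is HFHC against Chow, which addresses how the regimen changes gene expression in the liver. Log2 fold changes below are HFHC over Chow with their standard error (SE). Levels are CPM, counts scaled by library size, as mean ± SD with n = 3 per diet, and adjusted p values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

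Apoa4, an apolipoprotein of triglyceride-rich lipoproteins, rose from 85.1 ± 11 to 1918 ± 468 CPM, and Scd1, the desaturase that makes monounsaturated fatty acids, rose from 4986 ± 1861 to 17002 ± 4188 CPM. Fgf21, a hormone secreted by the liver, rose by 5.0 ± 0.54 on the log2 scale from a low level of 0.234 ± 0.113 CPM. Cyp3a11, a main drug-metabolizing cytochrome P450 of mouse liver, fell from 5035 ± 1155 to 191 ± 83.1 CPM, and the imprinted noncoding RNA Meg3 fell from 8.42 ± 1.17 to 0.733 ± 0.146 CPM. Of 14896 genes tested, 503 were higher and 491 lower in HFHC at an adjusted p under 0.05. Among these, 181 rose and 97 fell at least 2-fold.

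In 993 of the 994 changed genes every HFHC library lay on one side of every Chow library. Over all tested genes this share was 27.8%, where chance gives 10%. The share among changed genes follows largely from their selection by p value and is not separate support. The first principal component held 46.6% of the variance and separated the diets, and the second, with 16.6%, set Chow replicate 8 (-30.36) apart from Chow replicates 7 (11.19) and 9 (11.94). Without Chow replicate 8, 527 genes were higher and 553 lower, and 766 of the 994 genes remained called. Without Chow replicate 7 the counts were 207 higher and 154 lower, the smallest of the 6 fits that left out a library.

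**Figure D1:**
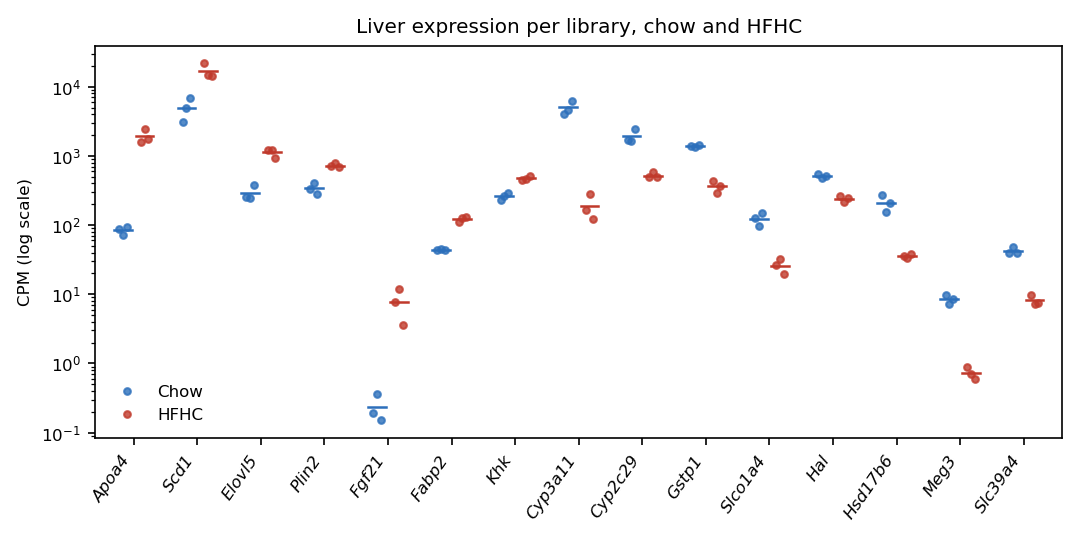
CPM of 15 genes on a log axis, with 1 point per library, blue for Chow and red for HFHC, and a bar at each diet's mean (n = 3). Genes run from Apoa4 on the left to Slc39a4 on the right.

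Besides Apoa4 and Fgf21, the largest increases under the rule for named genes were Stap1 (3.66 ± 0.29), Pls1 (3.25 ± 0.18), Chrna4 (3.0 ± 0.55), Rgs16 (2.82 ± 0.62), H2-Q1 (2.54 ± 0.18) and Adgrv1 (2.43 ± 0.32). Apoa4 lies on chromosome 9 at 46240696 to 46243459 (mm10, plus strand) with an adjusted p of 1.56e-05, and Fgf21 on chromosome 7 at 45613886 to 45615490 (minus strand) with an adjusted p of 0.00124. A noncoding gene on the opposite strand covers 34.8% of the exonic bases of Apoa4. Chrna4 encodes a nicotinic acetylcholine receptor subunit and ranged from 14.5 to 71.6 CPM among the HFHC livers, with a log2 fold change of 2.25 without HFHC replicate 1. H2-Q1 had values that were not whole in all 6 libraries, and counts summed over the 7 H2-Q genes had a log2 ratio of 0.40. The calls of Chrna4 (adjusted p = 0.0552) and Rgs16 (0.105) were lost without Chow replicate 7, and that of Rgs16 also without HFHC replicate 2 (0.0742). Rgs16 stood at 3.52 without Chow replicate 9.

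Under the same rule, which asks for at least 5 CPM in the higher diet and leaves out predicted names, the largest decreases were Cyp2b10 (-5.74 ± 0.68), Cyp3a11 (-4.72 ± 0.32), Meg3 (-3.51 ± 0.19), Cyp2c55 (-3.30 ± 0.34), Hsd17b6 (-2.55 ± 0.18), Cyp3a59 (-2.54 ± 0.28), Gstm3 (-2.42 ± 0.28) and Slc39a4 (-2.37 ± 0.14). Cyp2b10, on chromosome 7 at 25897620 to 25926624 (plus strand, adjusted p = 0.00195), had 9 counts over the 3 HFHC libraries and 435 over the 3 Chow libraries, and its log2 fold change ran from -6.67 without HFHC replicate 2 to -5.13 without Chow replicate 9. Cyp3a11 lies on chromosome 5 at 145854426 to 145879964 (minus strand, adjusted p = 0.000124). Meg3 lies on chromosome 12 at 109541001 to 109571726 (plus strand, adjusted p = 4.53e-05). Slc39a4, an intestinal-type zinc importer, stood at 8.18 ± 1.38 CPM in HFHC and 42.3 ± 5.05 CPM in Chow. Gstm3 had values that were not whole in all 6 libraries, so its level is uncertain.

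In the list of cholesterol synthesis and SREBP-2 target genes, fixed before the data were examined, 18 of 25 tested members rose, none fell and 7 did not pass. Adjusted over the list alone, 23 were higher. Hmgcs1, an enzyme of the early sterol pathway, rose by 1.09 ± 0.12 and Hsd17b7, which acts later in it, by 0.93 ± 0.11. All 25 members had a positive log2 fold change, with a median of 0.76 (camera adjusted p = 2.72e-32, adjusted p = 0.173 with an estimated correlation).

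In fatty acid synthesis 10 of 18 members rose and none fell, and 15 were higher when adjusted over the list alone. The named members were the desaturase Fads2 (1.71 ± 0.14), the elongase Elovl5 (1.94 ± 0.17) and Pnpla3 (3.89 ± 0.41, and 4.72 without Chow replicate 8, which held 14 of its 22 Chow counts). Scd1 rose by 1.77 ± 0.27 (chromosome 19, 44394455 to 44407879, minus strand, adjusted p = 0.00636). Fasn, the fatty acid synthase, had a log2 fold change of 1.18 ± 0.31 that did not pass (adjusted p = 0.0522), and passed without HFHC replicate 3 (0.0183) or Chow replicate 8 (0.0370). Fasn also passed with upper-quartile factors (0.0448), no count filter (0.0440), weighted limma-voom (0.0163) and the GC and length trend taken out (0.0206). Srebf1, which encodes SREBP-1, did not pass either (0.14 ± 0.11, adjusted p = 0.510). The list's median was 1.05 (camera adjusted p = 2.15e-25, adjusted p = 0.183 with an estimated correlation).

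Among genes of triglyceride synthesis and lipid droplets, 12 of 20 rose and none fell, 14 when adjusted over the list alone. The droplet coat protein gene Plin2 rose from 341 ± 65.3 to 726 ± 47.3 CPM, the lipase inhibitor G0s2 by 2.15 ± 0.24 and the acyltransferase Mogat1 by 2.87 ± 0.46. Cidec, whose product enlarges lipid droplets, rose by 3.39 ± 0.68 (adjusted p = 0.0204), a call lost without Chow replicate 7 (0.0807) or 9 (0.0707). Without Chow replicate 8 Cidec stood at 4.6 and Mogat1 at 3.47, and without HFHC replicate 2 Cidec stood at 2.59. Mogat1 was near the floor in Chow, with 14 counts over the Chow libraries and 120 over the HFHC libraries. The median of the list was 0.51 (camera adjusted p = 3.68e-13, adjusted p = 0.160 with an estimated correlation).

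Fatty acid uptake genes included 5 of 14 that rose and 1 that fell, or 6 and 2 adjusted over the list alone. Fabp2 rose by 1.48 ± 0.09, Fabp1 by 0.77 ± 0.10 and the nuclear receptor gene Pparg by 0.76 ± 0.15, while the lipoprotein lipase gene Lpl fell by 0.77 ± 0.11. The fatty acid translocase gene Cd36 rose by 1.26 ± 0.28 (adjusted p = 0.0300). Its call was lost without Chow replicate 7 (adjusted p = 0.110), 8 (0.0549) or 9 (0.0655), and that of Pparg without Chow replicate 7 (0.0808) or 9 (0.0656). The list median was 0.19 (camera adjusted p = 0.000383, adjusted p = 0.183 with an estimated correlation).

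Genes of fatty acid oxidation and PPAR alpha targets rose in 15 of 36 cases with no decrease, and in 25 when adjusted over the list alone. Besides Fgf21 these included Cpt1a, the mitochondrial entry enzyme for long-chain fatty acids (0.77 ± 0.09), and the peroxisomal thiolase Acaa1b (1.17 ± 0.16). The list median was 0.39 (camera adjusted p = 2.78e-15, adjusted p = 0.215 with an estimated correlation). Of 21 cholesterol efflux and lipoprotein genes 6 rose and 1 fell (7 and 1 adjusted over the list alone). Apoa4, Pltp (2.09 ± 0.18) and Apoc2 (0.98 ± 0.08) rose. Apoc2 shares 79.5% of its exonic bases with a gene on the same strand and had values that were not whole in all 6 libraries, so its level is uncertain. Apob fell by 0.43 ± 0.11 (adjusted p = 0.0453), a call lost in 5 of the 6 fits that left out a library (0.0718 to 0.175) and with the GC and length trend taken out (-0.17, adjusted p = 0.409). The call of Apob was also lost with upper-quartile factors and without the pseudogenes that match mitochondrial transcripts. The median of this list was 0.24 (camera adjusted p = 1.93e-12, adjusted p = 0.0920 with an estimated correlation).

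In the fructose and hexose uptake list 3 of 10 genes rose, or 4 adjusted over the list alone. Khk, the fructokinase, rose from 260 ± 29.1 to 477 ± 35.1 CPM (0.87 ± 0.10, adjusted p = 0.00191). Tkfc, the triokinase of the same pathway, rose too (0.88 ± 0.17), a call lost without Chow replicate 7 (adjusted p = 0.0525). The camera adjusted p was 0.00431, and 0.183 with an estimated correlation. Glycolysis and pentose phosphate genes rose in 6 of 19 cases (13 adjusted over the list alone), among them Pklr (1.58 ± 0.23), Pgd (0.79 ± 0.13) and Ldha (0.68 ± 0.09). Their median was 0.29 (camera adjusted p = 7.95e-09, adjusted p = 0.183 with an estimated correlation).

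Gluconeogenesis and insulin signalling genes as a list did not pass (camera adjusted p = 0.110, adjusted p = 0.752 with an estimated correlation). Of 16 members, Pcx rose (0.61 ± 0.11), and the insulin receptor substrate gene Irs1 (-0.90 ± 0.16) and Creb1 (-0.33 ± 0.08) fell, with 1 higher and 3 lower when adjusted over the list alone. Pck1 stood at 1260 ± 492 CPM in HFHC and 2223 ± 138 CPM in Chow (-0.82 ± 0.23), which did not pass (adjusted p = 0.0655) and passed without HFHC replicate 2 (0.00831) or with weighted limma-voom (0.0284). The call of Pcx was lost without Chow replicate 7 (0.0755) or 9 (0.0556), and that of Creb1 in each of the 6 fits that left out a library (0.0534 to 0.114) and with the GC and length trend taken out (-0.09, adjusted p = 0.511). That of Creb1 was also lost with no count filter and with DESeq2. The list passed as lower without Chow replicate 8 (camera adjusted p = 0.0110) or HFHC replicate 2 (0.00264).

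Among CAR and PXR targets of xenobiotic metabolism, 11 of 21 genes fell and 1 rose (13 and 1 adjusted over the list alone). The carboxylesterase Ces2a fell by 1.62 ± 0.10, Cyp3a11 by 4.72 ± 0.32 and Cyp2c29 by 1.89 ± 0.16. Cyp2b9 rose by 3.15 ± 0.45 to 3.34 ± 1.76 CPM. Ces2a had values that were not whole in all 6 libraries, so its level is uncertain. The list median was -0.48 (camera adjusted p = 1.90e-21, adjusted p = 0.160 with an estimated correlation). Counts summed over the 10 genes of the Cyp3a family stood at 656 ± 161 CPM in HFHC and 6082 ± 1146 CPM in Chow, and those over the 15 Cyp2c genes at 2527 ± 323 and 4894 ± 519 CPM. The sum over the 4 Cyp2b genes stood at 3.43 ± 1.84 and 5.84 ± 3.56 CPM, with the libraries of the diets overlapping.

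Genes of the NRF2 and glutathione list fell in 6 of 21 cases and rose in none, or 10 and 1 adjusted over the list alone. The named members were the glutathione S-transferases Gsta4 (-1.58 ± 0.11), Gstp1 (-1.93 ± 0.14) and Gsta2 (-2.21 ± 0.19). The list median was -0.30 (camera adjusted p = 1.31e-11, adjusted p = 0.183 with an estimated correlation). Gsta2 and Gstp1 had values that were not whole in all 6 libraries, so reads shared with near-identical genes leave their levels uncertain. Counts summed over the 4 Gstp genes were lower in each HFHC library, from 1979 ± 74.5 to 539 ± 107 CPM. The sum over the 4 Gsta genes stood at 1483 ± 115 CPM in HFHC and 1506 ± 193 CPM in Chow, with overlapping libraries. In Chow, Gsta2 (23.4 CPM) and Gsta4 (40.9 CPM) were each below the SD of that sum, so it cannot show whether they fell.

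Periportal hepatocyte genes fell in 9 of 21 cases and rose in none (14 and 1 adjusted over the list alone). They included Hsd17b6, the histidine-degrading enzyme Hal (-1.07 ± 0.10) and Etnppl (-1.48 ± 0.16). The median was -0.36 (camera adjusted p = 1.93e-13, adjusted p = 0.0920 with an estimated correlation). Of 19 pericentral genes 2 rose, among them Lect2 (0.56 ± 0.10), and Cyp1a2 (-0.45 ± 0.11) fell, the list did not pass (camera adjusted p = 0.614), and 2 were higher and 2 lower adjusted over the list alone. The call of Cyp1a2 was lost in 5 of the 6 fits that left out a library (0.0602 to 0.130), and that of Lect2 without Chow replicate 7 (0.0550). That of Cyp1a2 was also lost with upper-quartile factors. Amino acid catabolism and urea cycle genes fell in 9 of 31 cases and rose in 1, or 15 and 2 adjusted over the list alone. Hal, the glutaminase Gls2 (-0.86 ± 0.12) and Cth (-1.43 ± 0.22) fell, and Prodh2 rose by 0.47 ± 0.08, a call lost without Chow replicate 7 (0.0650). This list's median was -0.29 (camera adjusted p = 1.49e-06, adjusted p = 0.499 with an estimated correlation). Without the 9 members shared with other lists it no longer passed (22 tested, 4 lower, median -0.12, camera adjusted p = 0.0693).

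**Figure D2:**
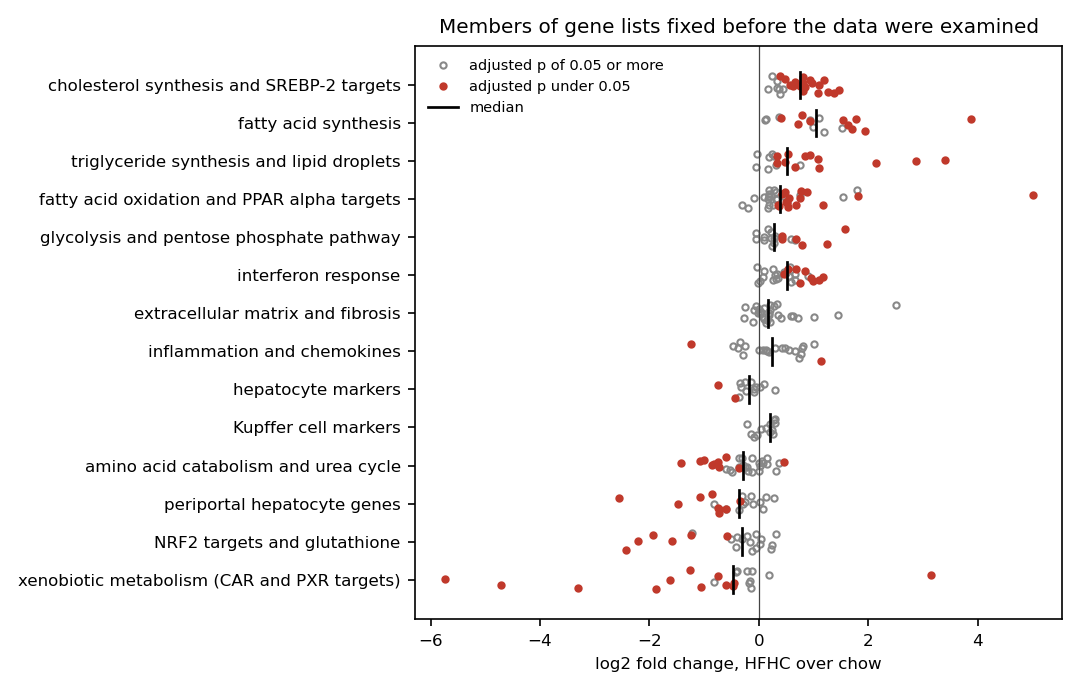
Log2 fold change (HFHC over Chow) of each tested member of 14 gene lists, 1 point per gene, filled red where the adjusted p was under 0.05 and open otherwise, with a black bar at the list's median.

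Interferon-induced genes rose in 9 of 29 cases and fell in none, and 19 were higher adjusted over the list alone. Oasl1 (0.96 ± 0.10), Ifi44 (1.17 ± 0.16) and Oas1a (1.10 ± 0.18) led, and the median was 0.52 (camera adjusted p = 3.54e-12, adjusted p = 0.308 with an estimated correlation). The inflammation and chemokine list did not pass (camera adjusted p = 0.227), with Cxcl9 higher (1.14 ± 0.15) and Ccl9 lower (-1.24 ± 0.13) among 22 genes, 1 and 1 also adjusted over the list alone. It passed as higher without HFHC replicate 1 (camera adjusted p = 0.0310). Acute phase genes went both ways: Saa2 (1.70 ± 0.10) and Hamp2 (1.17 ± 0.21) rose, and Itih3 and C3 (-0.62 ± 0.11) fell, among 27 (camera adjusted p = 0.815, 4 higher and 6 lower adjusted over the list alone). The calls of Hamp2 (adjusted p = 0.0555) and C3 (0.0568) were lost without Chow replicate 7. Saa2 had values that were not whole in all 6 libraries, and Saa1 of the same list was not called, so the level of Saa2 is uncertain.

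No gene of the 30 tested for extracellular matrix and fibrosis or of the 22 cell cycle genes passed, over all genes or adjusted over the list alone. The members with the smallest p were Smoc2 (0.62 ± 0.16, adjusted p = 0.0536) and Ccnd1 (0.59 ± 0.17, adjusted p = 0.0657). Smoc2 passed without HFHC replicate 3 (0.0179), with upper-quartile factors (0.0435), DESeq2 (0.0326), weighted limma-voom (0.0239) and the GC and length trend taken out (0.0477). Ccnd1 passed without Chow replicate 8 (0.00457), with DESeq2 (0.00886) and with weighted limma-voom (0.0170). Both lists had a camera adjusted p of 0.0423, against 0.799 and 0.701 as adjusted p with an estimated correlation. The matrix list no longer passed without HFHC replicate 1 (0.0617), 2 (0.603) or Chow replicate 9 (0.180). The cell cycle list no longer passed without HFHC replicate 1 (0.0876), 3 (0.0511), Chow replicate 7 (0.208) or 8 (0.0765).

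No member passed among Kupffer cell (13 genes, camera adjusted p = 0.210), hepatic stellate cell (13, 0.815), sinusoidal endothelial (14, 0.569), cholangiocyte (8, 0.373), T and NK cell (4, 0.838) or neutrophil markers (3, 0.541), and none passed adjusted over the list alone. Their members with the smallest p were Clec4f (0.30 ± 0.10), Colec11 (0.23 ± 0.12), Cdh5 (-0.16 ± 0.08), Ehf (-0.52 ± 0.29), Cd4 (-0.37 ± 0.17) and Lcn2 (0.75 ± 0.26), of which Lcn2 passed with DESeq2 (0.0464). The Kupffer list passed as higher without HFHC replicate 1 (camera adjusted p = 0.0498). The camera direction was opposite to the sign of the median for the stellate (median 0.01), T and NK (0.01) and neutrophil (-0.04) lists. Lgals3 rose (0.85 ± 0.17) among 15 markers of monocyte-derived and lipid-associated macrophages (5 adjusted over the list alone), whose median was 0.57 (camera adjusted p = 0.0139, adjusted p = 0.308 with an estimated correlation). The call of Lgals3 was lost without HFHC replicate 1 (0.0585) or 3 (0.0558), or Chow replicate 7 (0.0810) or 9 (0.0552).

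Ighm rose (1.45 ± 0.24) among 10 B lineage markers (camera adjusted p = 0.530, 1 adjusted over the list alone). Hba-a1 rose (0.37 ± 0.08) among 6 erythroid markers (0.0621, 1 adjusted over the list alone), a call lost in 5 of the 6 fits that left out a library (0.0522 to 0.128) and with the GC and length trend taken out (0.22, adjusted p = 0.146). The erythroid list passed as higher without HFHC replicate 2 (0.0296) or Chow replicate 9 (0.0375), and with limma-voom (0.0221) or weighted limma-voom (0.0216). Cfd was the single member higher among 6 adipocyte markers (camera adjusted p = 0.530), with 77 counts over the HFHC libraries and 1 count over the Chow libraries. Its call was lost without Chow replicate 7 (adjusted p = 0.0885) or 9 (0.0739), and 1 member was higher and 1 lower adjusted over the list alone. Among 14 hepatocyte markers Cps1 (-0.75 ± 0.12) and Apob fell, 6 were lower adjusted over the list alone, and the median was -0.19 (camera adjusted p = 0.01, adjusted p = 0.522 with an estimated correlation). This list no longer passed without HFHC replicate 2 (0.0570) or without members shared with other lists (0.134). Alb stood at 58693 ± 1063 CPM in HFHC and 58045 ± 8356 CPM in Chow.

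Sex-biased liver genes moved in both directions. Of 27 male-biased genes 6 fell and 2 rose, or 13 and 2 adjusted over the list alone. Hsd17b6, Gstp1 and Serpina1e (-2.12 ± 0.31) fell, and Cyp2u1 (0.42 ± 0.08) rose, a call lost without Chow replicate 7 (0.0718) or 9 (0.0696). The list median was -0.35 (camera adjusted p = 8.77e-08, adjusted p = 0.332 with an estimated correlation). Of 15 female-biased genes Cyp17a1 (2.38 ± 0.28), Cyp2b9, Abcd2 (1.56 ± 0.25) and Hamp2 rose, and Slco1a4 (-2.25 ± 0.20) and Cyp2b10 fell, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.373). That list passed as higher without HFHC replicate 1 (camera adjusted p = 3.89e-05).

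Bile acid genes did not pass as a list (24 genes, camera adjusted p = 0.373, 4 higher and 5 lower adjusted over the list alone). Its median was 0.00 and its mean -0.08, with the camera direction downward. The phospholipid exporter Abcb4 rose (0.60 ± 0.12), and the uptake transporter Slco1a4 and the nuclear receptor gene Nr5a2 (-0.40 ± 0.08) fell. Abcb4 and Slco1a4 had values that were not whole in all 6 libraries, so their levels are uncertain. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, ranged from 39.0 to 147 CPM in Chow and from 91.1 to 196 CPM in HFHC (0.90 ± 0.48, adjusted p = 0.313). It passed without Chow replicate 9 (1.83 on the log2 scale, adjusted p = 0.0123). The call of Abcb4 was lost without Chow replicate 7 (0.0894) or 9 (0.0738). That of Nr5a2 was lost without HFHC replicate 2 (0.0762) or 3 (0.0603), or Chow replicate 7 (0.0771) or 9 (0.0904).

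Several lists depended on Chow replicate 8. Dbp rose (1.26 ± 0.28) and Clock (-0.60 ± 0.08), Rora (-0.50 ± 0.07) and Cry1 (-0.49 ± 0.13) fell among 20 circadian clock genes, with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.815). Without Chow replicate 8, 6 clock genes were higher and 4 lower (camera adjusted p = 0.00628). Dbp stood at 45.2 CPM in Chow replicate 8, against 21.1 and 18.4 CPM in Chow replicates 7 and 9 and 62.3 to 74.2 CPM in HFHC. The call of Cry1 was lost in each of the 6 fits that left out a library (0.0836 to 0.118), and that of Dbp in 5 of them (0.0698 to 0.110). That of Cry1 was also lost with upper-quartile factors, no count filter, DESeq2, and limma-voom with or without sample weights. With the GC and length trend taken out the call of Rora was lost (-0.24, adjusted p = 0.0610) and Clock stood at -0.35 (adjusted p = 0.0241).

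Of 17 heat shock genes none passed, over all genes or over the list alone, with Serpinh1 having the smallest p (0.52 ± 0.18, adjusted p = 0.122, and 0.0148 without HFHC replicate 3 or 0.0455 with weighted limma-voom). The list median was 0.33 (camera adjusted p = 0.00379, adjusted p = 0.522 with an estimated correlation, and camera adjusted p = 0.0787 without Chow replicate 7). Without Chow replicate 8, 7 of them were higher. Among 22 genes of the unfolded protein response Atf3 rose (2.09 ± 0.25), also the single one adjusted over the list alone, and the median was 0.17 (camera adjusted p = 0.0423, adjusted p = 0.752 with an estimated correlation). Without Chow replicate 8, 8 were higher and 1 lower, and the list no longer passed without HFHC replicate 2 (0.0648), 3 (0.0797), Chow replicate 7 (0.201) or 9 (0.180). Nor did it pass with upper-quartile factors (0.0501), the filter at 1 CPM (0.0549) or the GC and length trend taken out (0.102).

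Atf3, Fosb (2.55 ± 0.40) and Btg2 (0.56 ± 0.11) rose among 16 immediate early genes, which tissue handling also raises, with 5 higher adjusted over the list alone (camera adjusted p = 0.00943, adjusted p = 0.332 with an estimated correlation). Without Chow replicate 8, 5 were higher, and the list no longer passed without HFHC replicate 2 (0.0551) or Chow replicate 9 (0.0974). The call of Btg2 was lost without Chow replicate 7 (0.0522). Fosb was near the floor in Chow, with 12 counts over the Chow libraries and 83 over the HFHC libraries. No ribosomal protein gene (31 tested, camera adjusted p = 0.108) or nuclear gene of oxidative phosphorylation (32 tested, 0.330) passed, over all genes or over the list alone. The oxidative phosphorylation list passed as higher with the clock index as a covariate (0.0233). Rpl5 (-0.35 ± 0.14) and Ndufb8 (0.27 ± 0.10) had the smallest p, and Rpl5 passed with weighted limma-voom (0.0444). The ribosomal list passed as lower without HFHC replicate 3 (0.00285) or Chow replicate 8 (0.0262), and with limma-voom (0.0347), weighted limma-voom (0.00350) and the GC and length trend taken out (0.000202).

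With 3 mice per diet and camera's preset correlation, 21 of the 39 lists tested passed, 15 higher and 6 lower, and with an estimated correlation none did. Genes higher in HFHC had shorter and more GC-rich transcripts (median length 2443 bases) than genes lower in HFHC (4902.5 bases, against 3091 bases over all genes), and 681 of the 994 calls remained when each library's trend on these properties was taken out, with all 994 signs kept and a median size of 0.59 against 0.62. With an index of clock phase as a covariate, 63 of the 994 calls remained and all 994 log2 fold changes kept their sign. Their median size was 0.52 and their median SE went from 0.11 to 0.17. These genes were selected by p value, so the kept signs in either fit are little separate support.

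The libraries of the diets also differed in technical measures. Every HFHC library held more counts than every Chow library. Pseudogenes that resemble mitochondrial transcripts took 7.16% ± 0.26 of the counts in HFHC and 8.49% ± 0.0872 in Chow. The 2 differences each had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The 10 most abundant genes took 17.0% ± 0.517 and 16.2% ± 0.503 of the counts (exact permutation p = 0.2), and 19219 ± 79.2 and 19076 ± 23.8 genes had at least 1 count (exact permutation p = 0.1).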

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

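The 994 changed genes (503 higher, 491 lower) became 938 to 1215 under other size factors, filters, DESeq2, limma-voom without weights, and the fits without abundant genes or mitochondrial-like pseudogenes. With upper-quartile factors 595 of 995 calls were higher (59.8%, against 50.6%). With sample weights limma-voom called 1494 genes, 790 of them lower, and the cause was not tested. An adjusted p under 0.01 left 282 (166 higher, 116 lower) and a fold of at least 1.5 left 535 (313 higher, 222 lower), since both are stricter. With each library left out in turn, 361 to 1080 genes were called, 207 to 527 higher and 154 to 553 lower, lowest without Chow replicate 7 and highest without Chow replicate 8. With the clock index as a covariate 65 genes were called, 35 higher and 30 lower. Of the 131 named genes 75 lost their call in that fit, among them Khk, Scd1, Fgf21, Plin2, Cpt1a and Pklr. These losses are not given gene by gene above. That fit has 3 residual degrees of freedom instead of 4, the median SE of the 994 genes went from 0.11 to 0.17, and 60.2% of the index's variance lies between the diets. With the GC and length trend taken out 889 genes were called. Of 39 lists, 21 passed with the preset correlation and 0 with an estimated correlation, and 15 to 23 passed under the other settings. Without shared members the unfolded protein response (camera adjusted p = 0.179), extracellular matrix (0.0691) and immediate early (0.0732) lists also no longer passed. With upper-quartile factors the matrix and cell cycle lists did not pass (each 0.0520), and with the filter at 1 CPM neither did the matrix (0.0770), immediate early (0.0567) and lipid-associated macrophage (0.0567) lists. With the clock index the median of the unfolded protein response turned to -0.19 (camera adjusted p = 0.0702) and that of the heat shock genes to -0.0508 (0.541), and the extracellular matrix (0.0714), cell cycle (0.0570), immediate early (0.160), hepatocyte (0.199) and lipid-associated macrophage (0.0714) lists no longer passed. The cause was not tested. The planned fit without mitochondrially encoded genes was not run because the table holds none.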

Other observations

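The gene groups of this paragraph and the genes named in it were chosen after their values were seen. Their counts and camera p values are therefore not independent evidence. Those p values were adjusted over the groups chosen this way alone, not over the fixed lists. Genes of MHC class I and peptide loading were higher in HFHC in 9 of 21 cases, among them H2-Q6 (0.84 ± 0.11), H2-Q7 (0.65 ± 0.09) and the peptide transporter gene Tap1 (0.71 ± 0.12), with a camera adjusted p of 2.17e-12 and an adjusted p = 0.0502 with an estimated correlation. With the GC and length trend taken out 5 were higher. H2-Q6 and H2-Q7 had values that were not whole in all 6 libraries, and the counts summed over the 7 H2-Q genes had a log2 ratio of 0.40. Terminal complement genes, whose products form the membrane attack complex, were lower in 5 of 7 cases, among them Hc (-0.51 ± 0.08), C8a (-0.57 ± 0.09) and C9 (-0.63 ± 0.11), with a camera adjusted p of 1.41e-05 and an adjusted p = 0.0915 with an estimated correlation. The call of C9 was lost without HFHC replicate 1 (0.0540) or Chow replicate 7 (0.0631). Of 13 UDP-glucuronosyltransferase genes 5 were lower and 1 was higher. Ugt1a9 (-1.83 ± 0.16) and Ugt1a5 (1.48 ± 0.11) went opposite ways, and each shares over 59% of its exonic bases with other genes of its cluster.

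Acetylcholine receptor genes were higher in 3 of 4 cases (Chrna4, Chrna2 at 1.27 ± 0.15 and Chrm3 at 2.64 ± 0.37, or 3.26 without Chow replicate 8), and aquaporin genes in 2 of 5 (Aqp4 at 1.45 ± 0.17 and Aqp8 at 1.44 ± 0.21). The lysophospholipid transporter gene Mfsd2a rose from 14.2 ± 7.17 to 76.8 ± 20.8 CPM and the citrate transporter gene Slc13a2 fell from 4.04 ± 0.581 to 0.357 ± 0.117 CPM. Beside Meg3, the noncoding RNA Rian of the same imprinted cluster fell by 3.61 ± 0.31 on the log2 scale. Apart from Chrna4 and Meg3, which the rule gave, these genes were chosen after their values were seen. Chow replicate 8 stood at 24.5 CPM for Per2, where the other Chow libraries had 6.72 and 9.62, at 12 CPM for Igfbp1, where they had 95.8 and 104, and at 54.8 CPM for Cish, where they had 6.41 and 2.45. The HFHC libraries ranged from 19.8 to 28.3 CPM for Per2, from 14.9 to 45.9 for Igfbp1 and from 3.75 to 35.6 for Cish.

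The tests below and their alternatives were chosen after the results were seen. Of the 10 ways to split the 6 libraries evenly, 1 gave as many as 994 changed genes, the real one, and the highest other gave 1. For the list tests 1 split gave as many as 21 lists, the real one, and the highest other gave 20. The other splits gave 10 to 20 lists, so many lists passed with the preset correlation whichever way the libraries were grouped. Each other split mixes the diets unevenly. Part of the diet difference then lies between its sides, and the rest widens the spread within them. The other splits therefore cannot show how many genes or lists pass without a diet effect. With 10 splits no share under 0.05 can arise.

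Fewer stellate and endothelial cells could lower Meg3 and Rian, but the lower quartile of the log2 fold change over their 27 markers was -0.12, against -3.51 for Meg3. Reads shared with the X-linked copy Gm27000 could also move counts away from Meg3, yet the summed counts had a log2 ratio of -3.54. C57BL/6J animals in 1 group would shift Nnt, whose log2 fold change was 0.06 (SE 0.0833).

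A lower share of hepatocytes could lower the drug metabolism genes, but the lower quartile of the log2 fold change over hepatocyte markers was -0.34, while the 11 called members fell by a median of 1.25 on the log2 scale. Over all 21 tested members the median was -0.48, nearer to that quartile, so a lower share stays open for the members with small falls. Reads shared between paralogs would leave a family sum unchanged. The summed Cyp3a counts had a log2 ratio of -3.21, but the summed Cyp2b counts one of -0.77 with overlapping libraries. Within Cyp2b, Cyp2b10 fell from 5.45 to 0.0964 CPM while Cyp2b9 rose from 0.372 to 3.34 CPM. The family sum therefore bears on Cyp3a and cannot decide for Cyp2b10. Values of Cyp2b10 and Cyp2b9 were whole in every library, which gives no sign of reads split between them. A difference in clock phase at sampling could move lipid, sterol and drug metabolism genes, and with the clock index as a covariate the median ratio of their log2 fold changes to those without it was 0.951 (quartiles 0.786 and 1.07 over 52 genes). That fit kept 10 of the 52 calls and left all 4 lists past the threshold, and it rests largely on Chow replicate 8. The median size went from 0.89 to 0.63 for triglyceride and lipid droplet genes, where 0 of 12 calls were kept. For sterol genes it went from 0.83 to 0.89 (2 of 18 kept). For fatty acid synthesis it went from 1.58 to 1.41 (3 of 10) and for drug metabolism from 1.44 to 1.335 (5 of 12). Dbp and Clock, which enter the index, were themselves called between the diets, so the fit cannot separate clock phase from diet. The time of day at collection is not given in the sources used here.

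Library bias in GC content and transcript length could put long, GC-poor transcripts among the lower genes. The libraries' rank correlation with GC content ranged by 0.4 within HFHC, more than the 0.318 between the diets' means, and by 0.275 within Chow, less than it. For transcript length the rank correlation ranged by 0.414 within HFHC and by 0.196 within Chow, against a difference of -0.3 between the diets' means. Such a bias therefore stays open, and HFHC replicate 3 (-0.073 for GC content, -0.368 for length) sets the wider range. With the trend taken out, 681 of the 994 calls and all 994 signs remained, with a median size of 0.59 against 0.62. The 994 genes were selected by p value, so their kept signs are little separate support. Among genes that lost their call were Kmt2c (-0.29, adjusted p = 0.136) and Nsd1 (-0.20, adjusted p = 0.110), both chosen after their values were seen.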
